A study of Rattus with 12 samples.

How the data were processed

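Total RNA from medullary thick ascending limbs of individual rats, 6 SS and 6 SS.BN1, was made into stranded total-RNA libraries and sequenced in pairs on an Illumina HiSeq instrument, per the labels' protocols. Tubules were selected by hand under a microscope after the outer medulla had been dissected and digested, per the labels. The submitters' processing notes name cutadapt, FastQC, TopHat2 2.1.1, StringTie and Cufflinks 2.2.1 and the build rn5, with no role or order. The gene and isoform tables have the columns and status words of Cuffdiff, per the file headers. The coordinates' build is not settled: 6832 rows carry names of contigs (AABR07) that belong to a later rat assembly, so coordinates are given as deposited, with 1 added to the start because starts are counted from 0 in the files (26 of 31 mitochondrial rows begin at another row's end).

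The expression values are FPKM made by the authors, 1 per strain and gene or isoform, and how the 6 libraries of a strain were combined is not given in the sources used here. The deposited tables also give the authors' test score, p-value and q-value per row and a log2 fold change of SS over SS.BN1, which was used only to check signs. Benjamini-Hochberg adjustment over the 13253 rows with status OK gave the authors' q-values to within 5.27e-07. A further table gives, per the file headers, the read count of each library (both mates), the percent of bases at Q30, the percent of reads mapped and a mean quality score. Libraries held 42.3 to 59.8 M reads.

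The gene table had 42915 rows, of which 13253 were tested by the authors and 29662 were not. Rows without a gene name (2101 of those tested) and rows joining several names (548) were kept. Of the 453 called rows, 410 had a symbol in a RefSeq gene table of the GRCr8 assembly, which was used for names only. Mitochondrial rows took 44.3% of all FPKM in SS and 46.9% in SS.BN1.

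Before the data were examined, a limma fit on log2 values per library, camera and fry gene set tests, leave-one-out fits and other splits of the libraries were planned, coded as SS.BN1 minus SS. Expression per library was not analysed here, so genes were called by the authors' q under 0.05, and ratios are given as SS over SS.BN1, as deposited. Log2 ratios and folds were computed from the authors' FPKM with no pseudocount, and no SD or n goes with them.

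Calls per chromosome and per gene list were compared with all other tested rows by two-sided Fisher's exact tests, with Benjamini-Hochberg adjustment over 21 chromosomes or 28 lists. Of 29 lists fixed before the data were examined, those with at least 5 tested members were tested; each member was matched by symbol to the tested row with the highest mean FPKM. As a second background, 10000 random lists matched in 20 bins of mean FPKM were drawn. Genes are not independent replicates, so these tests describe the tables. Strain means of library measures were compared by exact permutation over all 924 assignments, whose smallest p is 0.00216. Among the p-values computed here, only these permutation values rest on separate animals. How far the authors' p and q rest on variation between animals is not given in the sources used here.

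Named genes followed a rule fixed in advance. It took the 8 largest called differences per direction among genes with a symbol and at least 2 FPKM in 1 strain, up to 4 called members of each list by smallest q, 4 calls on and 4 off chromosome 1, fixed control genes, and the most abundant marker of each other cell type. Ties in q were broken by fold, a choice made after the data were seen. Some genes that the rule takes are not reported here. Other called list members and isoforms were named after their values were seen where a count was small.

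Alternatives planned in advance and run were a mean FPKM of at least 5, pseudocounts of 1 and 0.1, quantile normalization, median centring, summed isoform values and a fold of at least 1.5. A mean FPKM of at least 1, q under 0.01, leaving out rows that join several genes, matched random lists, leaving out members of more than 1 list, 10 further lists and 47 further proximal tubule genes were added after the data were seen. The scripts were tested on simulated p-values for 13253 rows with 200 changed, of which 99.5% were recovered with 5.24% false calls. The simulated changes were large and the rows independent, so this checks the code and says nothing of the authors' calls. Computation used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.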

Results

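RNA was sequenced from thick ascending limbs of the renal medulla, the nephron segment that reabsorbs salt through the Na-K-2Cl cotransporter, picked by hand from digested kidney tissue of 12 male rats aged 7 weeks on a diet with 0.4% NaCl. The Dahl salt-sensitive strain SS/JrHsdMcwi (SS) supplied 6 animals, and the consomic strain SS-Chr 1BN/Mcwi (SS.BN1), an SS rat whose chromosome 1 comes from the Brown Norway (BN) strain, supplied the other 6. The comparison asks how the tubule's transcriptome differs when chromosome 1 is exchanged, in a study of hypertension and kidney disease in SS rats. Read totals averaged 52.8 ± 3.69 M reads (SD, n = 6) in SS and 52.0 ± 5.68 M reads (SD, n = 6) in SS.BN1, exact permutation p = 0.784, two-sided. The expression tables hold 1 FPKM value per strain, so the values per gene below carry no error between animals, and q is the authors' adjusted p.

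Thick ascending limb preparations of SS rats had higher levels of many immediate early and heat shock genes (23 of 34 called) and kidney injury genes (14 of 23 called) than those of SS.BN1 rats. Proximal tubule markers were higher as well (13 of 21 called, median log2 ratio 1.27), and so were a few antigen presentation and interferon genes (6 of 39 called). The transport genes of the segment itself passed no test. The smallest called fold of any gene was 1.58, so smaller differences there are not excluded. In the authors' deposited table, 453 of 13253 tested genes had a q under 0.05, of which 440 (97.1%) were higher in SS and 13 were higher in SS.BN1. The called differences had a median fold of 2.59, computed from the authors' deposited table, and 95 were at least 4-fold. Adamts4, an aggrecan-cleaving protease, stood at 5.64 FPKM in SS and 0.237 in SS.BN1 (23.8-fold, q = 0.0124) in the authors' deposited table. Il6, a proinflammatory cytokine, followed there at 9.42 against 0.444 FPKM in the authors' deposited table (21.2-fold, q = 0.00502). Both folds rest on SS.BN1 values near 0: a pseudocount of 1 took the log2 ratio of Adamts4 from 4.57 to 2.42 and that of Il6 from 4.41 to 2.85.

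The other large differences toward SS included Csrp3, a muscle LIM protein (43.3 against 2.41 FPKM; log2 ratio 4.17, and 3.70 with a pseudocount of 1), and Csf3, a granulocyte growth factor (6.19 against 0.356), in the authors' deposited table. Chac1, a glutathione-degrading enzyme, stood at 11.2 against 0.657 FPKM, and Plaur, the urokinase receptor, at 26.2 against 1.62, in the authors' deposited table. Tgm1, a transglutaminase, had 3.11 against 0.201 FPKM and the neutrophil chemokine Cxcl2 had 26.5 against 1.73 in the authors' deposited table. An unnamed transcript on chromosome 5 (162100018 to 162100307) was listed at 6.91 FPKM in SS and at 0 in SS.BN1 in the authors' deposited table. The smallest p the authors' deposited table holds is 5e-05, shared by 249 genes, and the median log2 ratio of all tested genes was 0.00125.

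**Figure D1:**
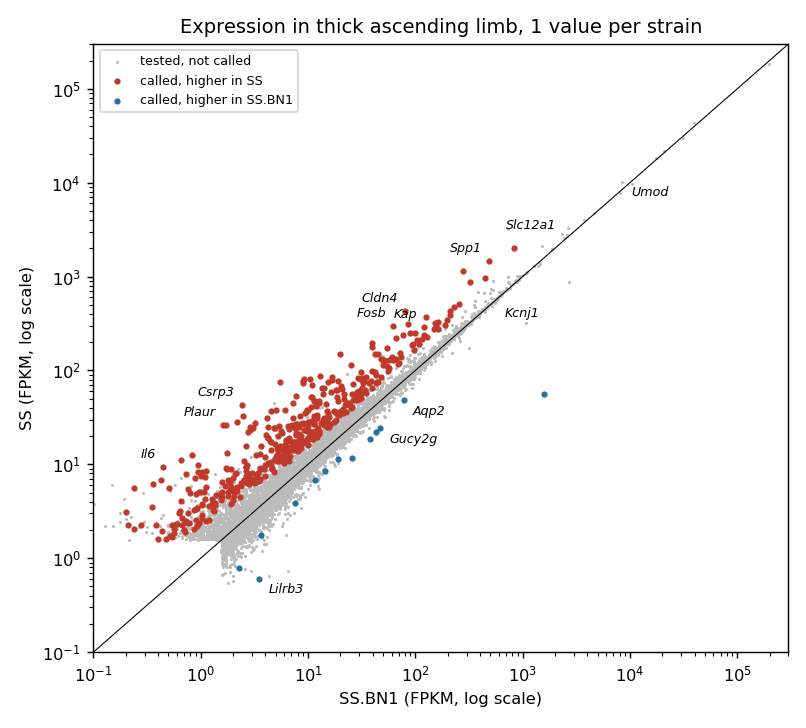
Expression of each tested gene in SS (vertical axis) against SS.BN1 (horizontal axis), both in FPKM on log scales, with 1 value per strain from the authors' deposited table and genes listed at 0 left out. Red points are called genes higher in SS (440 in all, 1 of them listed at 0 in SS.BN1), blue points the 13 higher in SS.BN1, and the line marks equal values.

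Immediate early and heat shock genes, which cells switch on within minutes of a stimulus or stress, held the highest share of calls among the fixed lists. Of 34 tested members, 33 had the higher value in SS, 23 were called higher in SS and none was called higher in SS.BN1 (26 called when adjusted over the list alone; Fisher's exact test, adjusted p = 6.18e-25). Fosl1, a subunit of the AP-1 transcription factor, stood at 28.6 against 2.16 FPKM, and Fosb, another, at 296 against 62.2, in the authors' deposited table (both q = 0.00266). Myc, a growth-promoting transcription factor, had 37.5 against 5.05 FPKM in the authors' deposited table. Hmox1, the haem-degrading oxygenase, had 70.7 against 10.9 FPKM there, per the authors' deposited table. The median log2 ratio of the list was 0.99, and that of proximal tubule markers, which moved the same way, was 1.27.

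Kidney injury markers were called higher in SS for 14 of 23 tested members, and all 23 had the higher value in SS (21 called when adjusted over the list alone; adjusted p = 2.11e-14, Fisher's exact test). Their median log2 ratio was 1.31, beside 1.27 for the proximal tubule markers. Cdkn1a, a cell cycle inhibitor, stood at 27.5 against 3.18 FPKM and Vcam1, an adhesion molecule, at 15.8 against 2.62, in the authors' deposited table. The fibrinogen chain Fga had 7.36 against 1.10 FPKM in the authors' deposited table. Antigen presentation and interferon genes were called higher in SS for 6 of 39 members (7 adjusted over the list alone; adjusted p = 0.0135). Those called included the antiviral gene Rsad2 (74.5 against 5.47 FPKM), the transcription factor Irf1 (176 against 39.4), Oasl (19.3 against 4.21) and the guanylate-binding protein Gbp2 (14.8 against 5.09), in the authors' deposited table.

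Antioxidant genes were called higher in SS for 5 of 33 members (5 adjusted over the list alone; Fisher's exact test, adjusted p = 0.0237), and 28 of 33 had the higher value in SS. Besides Hmox1 these were Txnrd1, a thioredoxin reductase (61.6 against 18.8 FPKM), Gclc, which makes the precursor of glutathione (81.4 against 30.4), Nfe2l2, their transcription factor (75.6 against 45.1), and the mitochondrial dismutase Sod2 (346 against 196), in the authors' deposited table. Genes of the unfolded protein response were called for 4 of 25 members (9 adjusted over the list alone; adjusted p = 0.0385). These were Chac1, Trib3 (3.51 against 0.353 FPKM), Atf4 (321 against 152) and Dnajb9 (43.8 against 23.6) in the authors' deposited table. Both calls were lost against random lists matched on mean FPKM, with adjusted p = 0.0917 for the antioxidant list and 0.0840 for the unfolded protein response. They were also lost without members of more than 1 list, with adjusted p = 0.216 and 0.0520, and the unfolded protein response reached 0.139 among genes with a mean FPKM of at least 5.

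Genes that define the thick ascending limb and its salt transport showed no call among 37 tested members, of which 1 had an unadjusted p under 0.05 (adjusted p = 0.851; median log2 ratio 0.05). Slc12a1, the Na-K-2Cl cotransporter, stood at 2571 FPKM in SS and 2406 in SS.BN1 (q = 1.00) in the authors' deposited table. Uromodulin (Umod), the most abundant protein of normal urine, had 10174 against 8492 FPKM, and the potassium channel Kcnj1 had 523 against 555, in the authors' deposited table. The sodium-hydrogen exchanger Slc9a3 had 244 against 232 FPKM in the authors' deposited table. Of 38 tested regulators of Na-K-2Cl cotransport, 1 was called (adjusted p = 1.00), in a row that joins the phosphodiesterase Pde4b with another gene (6.29 against 1.87 FPKM) in the authors' deposited table.

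Blood pressure candidate genes of rat chromosome 1 were called higher in SS for 3 of 21 tested members (4 adjusted over the list alone), short of the threshold as a list (adjusted p = 0.0911). These were Adm, the vasodilator peptide adrenomedullin (20.8 against 4.06 FPKM), the organic cation transporter Slc22a2 (18.2 against 6.27), and Sod2, in the authors' deposited table. Nox4, an NADPH oxidase on the same chromosome, had 1.90 against 0.926 FPKM with q = 0.145 in the authors' deposited table. The NADPH oxidase list had no call over all genes and 2 when adjusted over the list alone (6 tested, 2 with an unadjusted p under 0.05; adjusted p = 1.00). The 20-HETE and epoxyeicosanoid enzymes had 2 calls of 9, Cyp4a8 (10.2 against 4.37 FPKM) and a joined row of Cyp4a2 and Cyp4a3 (47.0 against 11.7), in the authors' deposited table. These enzymes have near-identical copies, so the split between them is uncertain. That list missed the threshold over all genes (adjusted p = 0.0911) and passed it among genes with a mean FPKM of at least 5 (adjusted p = 0.0478). The joined row is also a proximal tubule marker, and without members of more than 1 list 1 call of 7 remained (adjusted p = 0.417).

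The lists of energy metabolism held few calls. None of 74 nuclear genes of oxidative phosphorylation was called, and none had an unadjusted p under 0.05 (adjusted p = 0.344). Fatty acid oxidation had no call among 26 members (1 with an unadjusted p under 0.05; adjusted p = 1.00), and the tricarboxylic acid cycle had 1 of 29, the phosphatase Pdp1 (adjusted p = 1.00). Glycolysis had 3 calls of 19, each higher in SS: Hk2, a hexokinase (24.2 against 4.81 FPKM), the regulator Pfkfb3 (64.1 against 20.7) and the glucose carrier Slc2a1 (154 against 71.4), in the authors' deposited table. The list's adjusted p was 0.0895 and fell to 0.0322 with calls at q under 0.01. Cholesterol and fatty acid synthesis had 3 calls of 27, all higher in SS, among them Insig1, a sterol-sensing regulator (83.1 against 28.9 FPKM) in the authors' deposited table, with adjusted p = 0.148.

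Further lists did not pass. Prostaglandin and nitric oxide synthesis had 2 calls of 15, Ptgs2 and Ddah1 (adjusted p = 0.183), the renin-angiotensin system 1 of 8, the aminopeptidase Anpep (adjusted p = 0.400), and extracellular matrix genes 1 of 25, the protease Adamts1 (adjusted p = 0.851). Cell cycle genes had no call among 29 (none with an unadjusted p under 0.05; adjusted p = 0.851), and their median log2 ratio was -0.18.

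**Figure D2:**
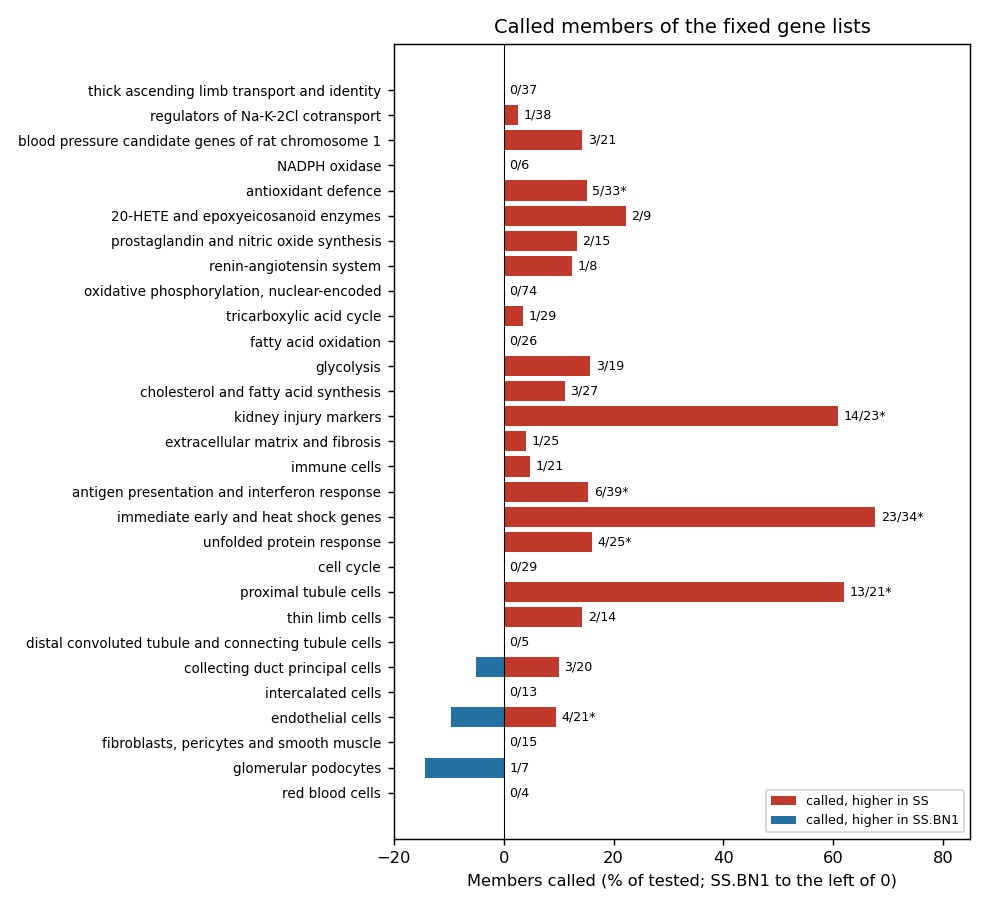
Share of the tested members of each fixed gene list with a q under 0.05 in the authors' deposited table, in percent, with members higher in SS to the right of 0 (red) and members higher in SS.BN1 to the left (blue). Labels give called over tested members and a star marks lists with an adjusted p under 0.05 by Fisher's exact test, such as 23 of 34 immediate early and heat shock genes; red blood cells, with 4 tested members, were not tested as a list.

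Markers of the proximal tubule, a neighbouring segment, were higher in SS, while endothelial, immune, principal and intercalated cell markers had median ratios below 0. Of 21 tested proximal tubule markers, 13 were called, all 21 had the higher value in SS, and the median log2 ratio was 1.27 (17 called when adjusted over the list alone; Fisher's exact test, adjusted p = 1.09e-13). Kap, the most abundant of them, stood at 290.3 against 120.5 FPKM and the amino acid carrier Slc7a13 at 96.2 against 31.1, in the authors' deposited table. The urate transporter Slc22a12 had 7.11 against 1.98 FPKM and the endocytic receptor Lrp2 had 7.86 against 2.83 in the authors' deposited table. The direction was that of the called stress, injury and interferon genes above.

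Endothelial markers had 4 calls of 21, 2 in each direction (6 adjusted over the list alone; adjusted p = 0.0237), with a median log2 ratio of -0.20. Tek, the angiopoietin receptor, stood at 6.78 FPKM in SS and 11.6 in SS.BN1, and Podxl at 11.4 against 19.0, in the authors' deposited table. Tm4sf1 (21.8 against 10.8 FPKM) and the water channel Aqp1 (138 against 74.1), which proximal tubules and thin limbs also express, were higher in SS in the authors' deposited table. The list's call was lost without members of more than 1 list (adjusted p = 0.280) and at q under 0.01 (adjusted p = 0.752). Immune cell markers had 1 call of 21, Cd14, higher in SS (adjusted p = 0.807), yet 18 of 21 had the lower value in SS and their median log2 ratio was -0.36. The most abundant of them, Cd74, had 358 against 349 FPKM in the authors' deposited table.

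Principal cells of the collecting duct had 3 calls of 20 (adjusted p = 0.0911), with Elf3 and Krt18 higher in SS and the water channel Aqp2 higher in SS.BN1 (48.1 against 78.3 FPKM) in the authors' deposited table. Intercalated cell markers had no call among 13 (1 with an unadjusted p under 0.05; adjusted p = 1.00), with a median log2 ratio of -0.22. Thin limb markers had 2 calls of 14, Aqp1 and the tight junction protein Cldn4 (426 against 80.6 FPKM) in the authors' deposited table, with adjusted p = 0.174. No marker of the distal convoluted tubule (5 tested, none with an unadjusted p under 0.05) or of fibroblasts, pericytes and smooth muscle (15 tested, 3 with one) was called, both with adjusted p = 1.00. Podxl was the 1 call among 7 podocyte markers (adjusted p = 0.378), and the red blood cell gene Hba-a1 had 83.6 against 82.8 FPKM in the authors' deposited table.

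Named genes higher in SS.BN1 were few and mostly differed by about 2-fold. Ctss, the lysosomal protease cathepsin S, stood at 11.6 FPKM in SS and 25.6 in SS.BN1, and Fabp4, a fatty acid carrier of adipocytes and endothelium, at 22.0 against 43.2, in the authors' deposited table. The apelin receptor Aplnr had 1.75 against 3.64 FPKM, the semaphorin Sema3d 3.85 against 7.62 and the exchanger regulatory factor Slc9a3r2 8.40 against 14.5, in the authors' deposited table. Lilrb3, an immunoglobulin-like receptor, and a row that holds Gvin1, an interferon-inducible GTPase, both on chromosome 1, had the largest folds among genes with a symbol, 5.84 and 2.91, in the authors' deposited table. Both belong to families with similar copies, among which reads can be split, so their values are uncertain.

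Chromosome 1, the chromosome in which the strains differ by design, held 67 called genes among 1778 tested (3.77%, 95% Clopper-Pearson interval 2.93 to 4.76). Other chromosomes held 386 among 11475 (3.36%), an odds ratio of 1.12 (Fisher's exact test, two-sided, p = 0.400, adjusted over 21 chromosomes 0.723). No chromosome passed after adjustment; the lowest adjusted p was 0.0636, for chromosome 17 with 23 of 371 called and for chromosome X with 4 of 384. Csrp3 (1, 104147206 to 104166367), Plaur (1, 81328183 to 81344708) and Fosl1 (1, 220826560 to 220838079) led the calls higher in SS on this chromosome in the authors' deposited table. Coordinates are as deposited, and their genome build is not settled.

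**Figure D3:**
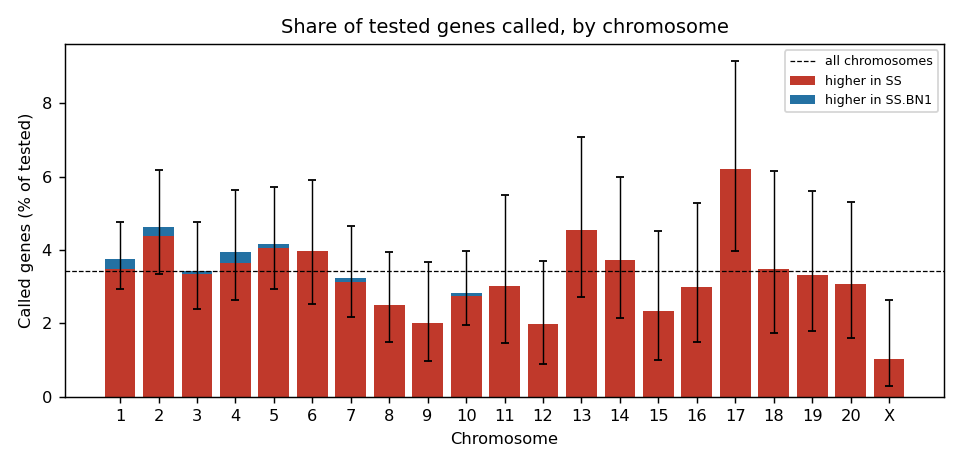
Genes with a q under 0.05 in the authors' deposited table as a percentage of the genes tested on each chromosome, split by direction (red higher in SS, blue higher in SS.BN1). Whiskers are 95% Clopper-Pearson intervals and the dashed line is the share over all chromosomes; chromosome 1 stands at 3.77%, near the line.

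Of the 67 called genes on chromosome 1, 62 were higher in SS (92.5%, interval 83.4 to 97.5; exact binomial test against an even split, p = 1.42e-13, with genes not independent). Elsewhere 378 were higher in SS and 8 in SS.BN1 (97.9%), so calls toward SS.BN1 were more frequent on chromosome 1 (odds ratio 3.81, Fisher's exact test, p = 0.0302). The 5 genes higher in SS.BN1 were Lilrb3 (73609740 to 73619596), the Gvin1 row (173233717 to 173347369), the receptor guanylate cyclase Gucy2g (276186888 to 276228574), an unnamed transcript (275976574 to 275981562), and a row of small RNAs (224921135 to 224924588). That small RNA row had 55.8 FPKM in SS and 1565 in SS.BN1 in the authors' deposited table, and FPKM of RNAs this short is uncertain. By the same exact test the excess was lost among genes with a mean FPKM of at least 5 (p = 0.0633) and without rows that join several genes (p = 0.205). It stayed with calls at q under 0.01.

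**Figure D4:**
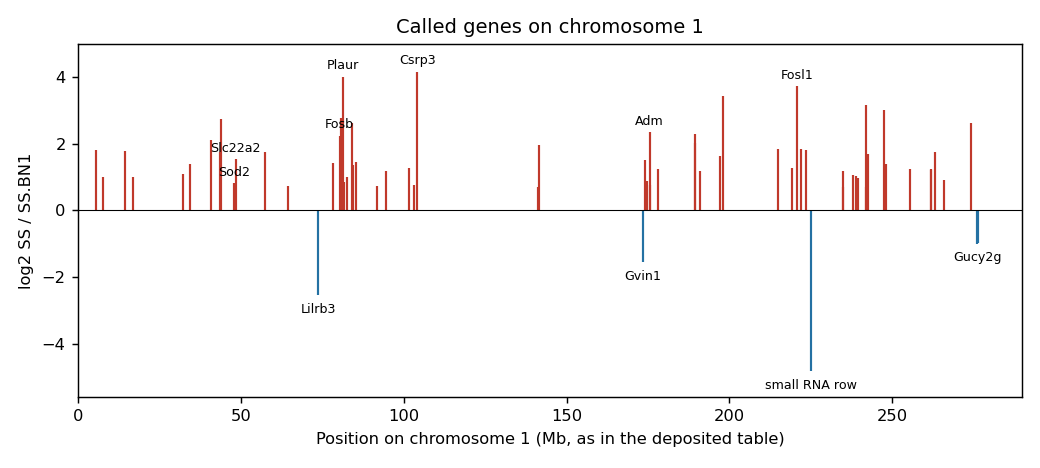
Called genes along chromosome 1, with position in megabases as in the authors' deposited table on the horizontal axis and the log2 ratio of SS over SS.BN1 on the vertical axis. Red lines are the 62 genes higher in SS and blue lines the 5 higher in SS.BN1. The unnamed transcript ends at 275981562 and Gucy2g starts at 276186888, so their lines stand close together without the loci being adjacent.

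Single isoforms gave the same direction with fewer calls. The authors' deposited table of isoforms had 249 of 23688 tested isoforms with a q under 0.05, 246 higher in SS and 3 higher in SS.BN1. The annotated isoforms of Adamts4 (5.05 against 0.185 FPKM), Il6 (9.42 against 0.444) and Chac1 (11.2 against 0.657) had some of the largest differences in the authors' deposited table. The 249 isoforms belonged to 242 genes, of which 240 were also called as genes, and 247 of 247 isoforms of those genes had the gene's direction. Gene values matched the summed isoform values within 0.1% for all but 6 genes, so this agreement is no separate evidence. No called isoform was found for 213 of the called genes. All 3 isoforms higher in SS.BN1 lay on chromosome 1 (Gvin1, the unnamed transcript, and an isoform at the Lilrb3 locus), among 38 called there (Fisher's exact test of direction against chromosome, p = 0.00332). These loci were already among the genes called higher in SS.BN1, so the isoform test repeats the gene test in part.

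The mapping rate averaged 85.85% ± 0.339 (SD, n = 6) in SS libraries and 85.3% ± 0.522 (SD, n = 6) in SS.BN1 libraries, exact permutation p = 0.0649, two-sided, adjusted over 4 measures 0.156. It fell under the threshold without SS replicate 5 (exact p = 0.0390), SS.BN1 replicate 4 (0.0433) or SS.BN1 replicate 5 (0.0216). The share of bases at Q30 was 89.7% ± 0.227 (SD, n = 6) against 89.4% ± 0.396 (SD, n = 6), exact permutation p = 0.0779, adjusted 0.156. Without SS replicate 5 or SS.BN1 replicate 5 it reached exact p = 0.0173 and 0.0433. Mean base quality did not differ at the threshold (34.0 ± 0.0490 against 34.0 ± 0.0969, SD, n = 6 each; exact permutation p = 0.186).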

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

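The lowest SS library stood apart from the other 5 in base quality. Its share of bases at Q30 was 89.3% and its gap to the next library was 0.654 of the group's range, above Dixon's critical value. The same library, SS replicate 5, had a mean quality score of 33.9 with a gap of 0.673 of the range. It lies inside the range of all 12 libraries, since SS.BN1 replicates 3 and 6 were lower on both measures (89.0% and 88.8% of bases at Q30). Chance marks about 5% of groups in this way, and the 2 measures describe the same bases.

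Rows outside the authors' test were listed at 0 in 1 strain and at 100 FPKM or more in the other. AABR07061821.1 (chromosome 4, 147644812 to 147670805) had 439 FPKM in SS, the small RNA RF01186 (6, 86785771 to 86810808) had 118 in SS, and RF00016 (8, 44990014 to 44993179) had 108 in SS, per the authors' deposited table. The mitochondrial row AY172581.7 had 366 FPKM in SS, per the authors' deposited table. In SS.BN1, the mitochondrial rows AY172581.14 and AY172581.11 with AY172581.17 had 515 and 1850 FPKM, per the authors' deposited table.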

How the results depend on the processing

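The gene count fell from 453 to 294 and the isoform count from 249 to 165 with q under 0.01, a setting chosen after the data were seen, with 288 genes higher in SS and 6 higher in SS.BN1; fewer calls follow from a stricter threshold. With a mean FPKM of at least 5, 345 genes were called, of which 341 were among the 453. Pseudocounts, quantile normalization, median centring and summed isoforms leave the authors' q as it is, so they say nothing of the calls' stability. They moved 151 of 380 log2 ratios of named genes by more than 0.1, 145 of these toward 0. A fold of at least 1.5 removed no gene call, since the smallest called fold was 1.58, and a mean FPKM of at least 1 left out 2 tested genes, neither of them called, so neither setting tests the calls. Gene lists past the threshold numbered 7, 5 against matched random lists and 4 without members of more than 1 list; the cause was not tested. Of 192 list results under alternatives, 183 stayed on their side of the threshold, 7 lost a call and 2 gained one. The 192 include the fold setting and the mean FPKM of at least 1, which could hardly change a list result, so the tally overstates stability. The share of calls on chromosome 1 and the majority of them toward SS kept their side. The excess toward SS.BN1 was lost in 2 settings (Fisher's exact test, p = 0.0633 with a mean FPKM of at least 5, 0.205 without joined rows). It stayed at q under 0.01. Without 1 library each, the difference in mapping rate ranged from 0.37 to 0.67 percentage points and that in reads from -1.18 to 2.32 M. Array weights, moderation without trend, covariates for label number and depth, an estimated correlation, leave-one-out of expression, other splits and pairing were not run, since expression per library was not analysed here. Replicate numbers follow accession order and pair no animals.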

Other observations

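Groups of genes put together after the calls were seen cover 70 of the 453 calls, 10 of them on a fixed list as well, and their counts are given without a test because of that choice. NF-kB targets, cytokines and chemokines had 34 calls of 51 tested, all higher in SS. Cxcl10, a T cell chemokine, stood at 150 against 19.8 FPKM, the interleukin Il1b at 24.3 against 3.05 and the NF-kB inhibitor Nfkbia at 133 against 47.4, per the authors' deposited table. Genes that restrain mitogen-activated kinases had 7 calls of 16, among them Dusp5 (37.7 against 6.13 FPKM, per the authors' deposited table). Actin and serum response factor targets had 8 of 19, ATF4 targets 8 of 26, and growth factor receptor ligands and receptors 3 of 9, led by Hbegf (77.0 against 8.93 FPKM, per the authors' deposited table). Calls in these lists were all higher in SS.

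Hypoxia-inducible genes had 4 calls of 19, all of them named above, while Vegfa had 200 against 188 FPKM, per the authors' deposited table. Metallothionein-related genes were few, but Mt1 had 1144 against 276 FPKM and Mt2A 2038 against 836, per the authors' deposited table. Clock genes had 3 calls of 16, Nfil3, Arntl and Bhlhe40, while Dbp had 71.8 against 92.2 FPKM and Per3 32.0 against 44.0 without a call, per the authors' deposited table. None of 65 cytosolic ribosomal protein genes was called, nor any of 8 mitochondrially encoded ones, and 0 of either had an unadjusted p under 0.05. Havcr1, the injury marker KIM-1, had 6.02 against 0.149 FPKM with q = 0.0708, per the authors' deposited table.

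All tests in the paragraphs that follow were chosen after the results were seen. The first pattern is that 440 of 453 called genes were higher in SS, among them 23 immediate early and heat shock genes. Immune cells as a whole, carried along in the SS libraries, are argued against. The median log2 ratio of the 21 tested immune markers was -0.36 (bootstrap interval -0.51 to -0.28). That median speaks for the markers together and cannot exclude a single immune cell type. Cd14, the only immune marker called, was higher in SS. The bootstrap intervals here and below resample genes, each with 1 value per strain, and hold no spread between animals. Proximal tubule material with equal expression per cell stays open for the immediate early and injury genes. The median log2 ratio of all 56 tested ones, called or not, minus that of the 18 proximal tubule markers in no other list was -0.28 (bootstrap interval -0.44 to 0.22). Ratios leave out how much of each gene the limb itself expresses, so this comparison cannot decide the question. Of 440 called genes outside the proximal tubule list, 121 exceeded the highest of the 18 markers (1.86). Calls favour large ratios, so this count excludes nothing. A stress response during dissection and digestion that differed between the strains' preparations may account for the 23 called immediate early and heat shock genes, and cannot be told apart from an untested strain difference in the living kidney, because both predict these calls and no value per library was analysed.

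The second pattern is the higher level of proximal tubule markers in SS, led in abundance by Kap at 290.3 against 120.5 FPKM in the authors' deposited table. More proximal tubule material in the SS libraries may account for it: 28 tested proximal tubule genes from outside every earlier list had a median log2 ratio of 0.90 (bootstrap interval 0.47 to 1.09), with 26 of 28 higher in SS, 7 called, and the most abundant, Folr1, lower in SS without a call (203 against 262 FPKM, per the authors' deposited table). A lower share of thick ascending limb cells, with all other cell types raised alike, is argued against by markers in no other list. The median of 18 proximal tubule markers lay 1.58 above that of 18 endothelial ones (permutation p = 1e-05, the smallest 100000 permutations give). The gap to 20 immune markers was 1.65 (permutation p = 3e-05). Both tests shuffle marker labels and hold no spread between animals. Proximal tubule material in place of limb cells would leave such gaps too, so they cannot exclude it. The 37 tested limb genes had a median log2 ratio of 0.05 and no call, so no fall in them was seen, though a small one is not excluded. Hand selection under the microscope would be meant to exclude proximal tubules, and 3 of the 21 fixed markers also belong to other lists. Regulation of these genes by strain stays open as an untested explanation, since it can raise proximal tubule genes together as well.

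The third pattern concerns chromosome 1 and a reference genome from the BN strain, to which SS reads may map less well there. As the whole cause of the 67 calls there this is argued against, since poorer mapping would lower SS values. Of these calls, 92.5% were higher in SS (Clopper-Pearson interval 83.4 to 97.5, genes not independent). Elsewhere 97.9% of calls were higher in SS too, so this majority was not particular to chromosome 1. It cannot exclude a smaller part for mapping beside another cause. For the 5 genes higher in SS.BN1, of which the Lilrb3, Gvin1 and small RNA rows have uncertain values, the excess on chromosome 1 (Fisher's exact test, p = 0.0302) was lost at a mean FPKM of at least 5 (p = 0.0633) and without joined rows (p = 0.205), stayed at q under 0.01 (p = 0.000291), and cannot be told apart from regulation by the introduced chromosome, because both predict it. The mapping rate was 0.55 percentage points higher in SS, short of the threshold, and does not settle the question either way. Regulation by chromosome 1 genes stays open as an untested explanation.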
